A study of Mus musculus with 8 samples.

How the data were processed

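Cortical cells of newborn GAD67-EGFP heterozygous mice were dissociated and sorted on GFP fluorescence, and total RNA was extracted from the sorted cells without culture, per the labels' protocols. The RNA was reverse-transcribed and transcribed in vitro with digoxigenin-labelled nucleotides, a step that amplifies it and can change the relative signal of transcripts, per the labels' protocols. The labels give 4 samples of GFP-positive and 4 of GFP-negative cells, numbered 1 to 4 in each group, and the design text calls them biological replicates. Whether a replicate is 1 pup or a pool, and the array type, scanner and feature extraction software, are not given in the sources used here.

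Each of the 4 deposited array tables holds 33315 rows for 1 GFP-negative and 1 GFP-positive array, of which 33012 are gene probes and 303 are controls. Probe brightness is given as a linear signal intensity, per the file headers, and the authors left array medians unequal, so no scaling between arrays was seen in it. No gene probe had a signal below 0, while some control spots did. A background step may therefore have been applied, but none is recorded. A signal-to-noise score is given for each spot, per the file headers. Whole-number quality flags were also deposited for each spot. The authors' deposited series matrix holds a ratio for each probe. For every array this ratio equals the signal divided by the array's median over gene probes with a flag under 5000, so its scale, centring and direction are known from the comparison. It was used as an alternative.

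Signals were set to at least 1, transformed to log2 and quantile normalized over the 8 arrays. Probes with a signal-to-noise score of at least 3 on at least 4 of the 8 arrays, whatever their group, were tested, which left 16875. Groups were compared with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes, no block), and p-values were adjusted by the Benjamini-Hochberg method over the tested probes, with a threshold of 0.05. Adjusted p values in the text come from this fit unless another is named, and differences are GFP-positive minus GFP-negative. Where a probe was not above background on any array of a group, its fold is given as a bound. It compares the bright group's mean with a mean over the dim group's arrays. Each dim array enters with the higher of the probe's own signal and the lowest signal among probes above background. Such a bound allows for background only where a dim array read under that lowest signal, and otherwise equals the measured fold. The spread between arrays is not covered, so a smaller fold is possible. Correlations and detected-probe counts describe the arrays, and single values were compared by exact permutation tests.

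The procedure was tested on simulated data for this comparison, with 200 of 16875 probes changed. It recovered 31% of the 100 probes changed by 1 on the log2 scale and 82% of the 100 changed by 2, with 5 false calls among 118. Differences of about 2-fold were therefore often missed in this simulation. Its arrays were drawn independently of each other and few probes changed, while 14.5% of the tested probes passed in the data. The adjustment over probes is less strict when more of them change. These rates therefore need not hold for the real comparison.

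Whether the replicate numbers pair the samples was checked before the calls of the fits were compared. The deviations of same-numbered arrays from their group means correlated at 0.517, 0.455, 0.347 and 0.441 for replicates 1 to 4, against −0.389 to 0.162 for the 12 other combinations. Each array correlated best with its own number, so the numbers were taken to pair the samples. The pairing comes from this check and from the array tables, each of which holds 1 number. Values with the replicate number as a block are given where they change a call or move a count by more than 1.5 times.

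Most probes carry a Celera gene identifier (27930) or the accession of a RIKEN cDNA (4181), and were kept under these. Gene symbols were taken from the reference table of assembly GRCm38.p6 by RefSeq transcript, synonym or symbol. They matched 317 probes of 311 genes, or 0.96% of the gene probes, of which 163 probes of 160 genes were tested. Of these 317, 311 matched by RefSeq transcript. Ntn1 was matched through a cDNA accession listed as its synonym. Where a gene had several tested probes, the one with the highest mean signal was used; this applied to Ccl21b and Prr18, whose probes had differences of the same sign.

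The rule for the genes to be named was fixed before the data were examined. It took the genes of GABA synthesis and excitatory neurons that check the sort, and members of 29 gene lists for cell types and processes. It also took the 10 genes with the highest and the 10 with the lowest difference among those past the threshold with the same sign in all 4 pairs. The highest and lowest genes were thus picked from these same data by the size of their difference. Gad1, Gad2, Slc32a1, Neurod6, Tbr1 and Slc17a7 were not among the matched symbols and are not analysed here, so the sort labels were not checked by them. Of 363 genes named in 22 of the lists, 5 were matched. No list had 3 tested members, so the planned camera and fry tests of the lists were not run.

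Alternatives were other scalings, the series matrix ratios, other filters, treatment of flagged spots, an offset, a floor, an intensity trend with a robust prior, the replicate block, other thresholds, and leaving out each array and each pair. Scaling to the mean of the 15 reverse transcription kit control rows, the hybridization batch as a block, the fits within each batch and detection at 5 times the noise were chosen after seeing the data. Their effects are given in the closing section. The split into batches was read from 3 hybridization control rows, not from a label.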

Results

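The neonatal cerebral cortex of GAD67-EGFP heterozygous mice was profiled at postnatal day 0. In this line EGFP is placed under the control of the gene for GAD67, an enzyme that makes the inhibitory transmitter GABA, so that GABAergic neurons fluoresce. Dissociated cortical cells were separated by flow cytometry into a GFP-positive and a GFP-negative fraction, and RNA from 4 biological replicates of each fraction was amplified, labelled with digoxigenin and measured on 8 one-colour arrays with 33012 gene probes each. The comparison asked which transcripts differ between cortical GABAergic neurons and the remaining cells of the same tissue. Below, the GFP-positive fraction is called GABAergic neurons by its sort alone, since no marker gene of these neurons was matched to check its purity. The GFP-negative fraction is a mixture that can hold excitatory neurons, progenitors, glia, vascular cells and blood cells.

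The numbers of probes above background did not differ clearly between the fractions. A signal at least 3 times the noise was found for 17229.5 ± 555.6 probes on the GFP-negative arrays and 16703.2 ± 362.7 probes on the GFP-positive arrays (SD, n = 4 each; two-sided exact permutation p = 0.171). This test leaves out the pairs and cannot show equality. The GFP-positive array had fewer such probes in replicates 1, 2 and 3, and more in replicate 4 (16737 against 16473). Median gene signals were 839.6 to 1079 on the GFP-negative arrays and 661.6 to 1052 on the GFP-positive arrays (two-sided exact permutation p = 0.486). The number of arrays limits the precision of every value. Across the tested probes, normalized log2 signals correlated at r = 0.945 to 0.972 between GFP-negative arrays, at 0.943 to 0.969 between GFP-positive arrays, and at 0.874 to 0.922 between arrays of different fractions; these are correlations across probes, which are not independent replicates.

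The fractions differed at many probes, and most of the differences of at least 2-fold were toward lower signal in GABAergic neurons. Of 16875 tested probes, 2441 passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, 906 higher and 1535 lower in GFP-positive cells. Of these, 608 were at least 2-fold higher and 1302 at least 2-fold lower. In all 4 same-numbered pairs of arrays the difference had the same sign for 904 of the 906 higher and 1531 of the 1535 lower probes. With the replicate number as a block, which fits the pairs, 4043 probes passed (1830 higher and 2213 lower), and 2390 of the 2441 were among them. The share of calls that were higher was 37.1%, against 23.6% when arrays were scaled to the reverse transcription kit control spots (439 higher, 1424 lower). It was 53.0% when the pairs were fitted after median scaling (2202 higher, 1954 lower). Without replicate pair 3 the count was 1529, with 462 higher, and without replicate pair 1 there were 521 higher.

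The hybridization control spots split the arrays into 2 batches, each holding both fractions. Their mean log2 signal was 15.95 to 16.27 on the arrays of replicates 1 and 2, and 17.13 to 17.35 on those of replicates 3 and 4. With this batch as a block 3361 probes passed limma's test (1434 higher, 1927 lower). Within replicates 1 and 2 alone 1088 probes passed (339 higher, 749 lower), and within replicates 3 and 4 alone 1173 passed (354 higher, 819 lower). Of the 1088 and 1173 probes called within the batches 693 were shared, none with opposite directions, against 43.5 expected in the same direction for independent lists.

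**Figure D1:**
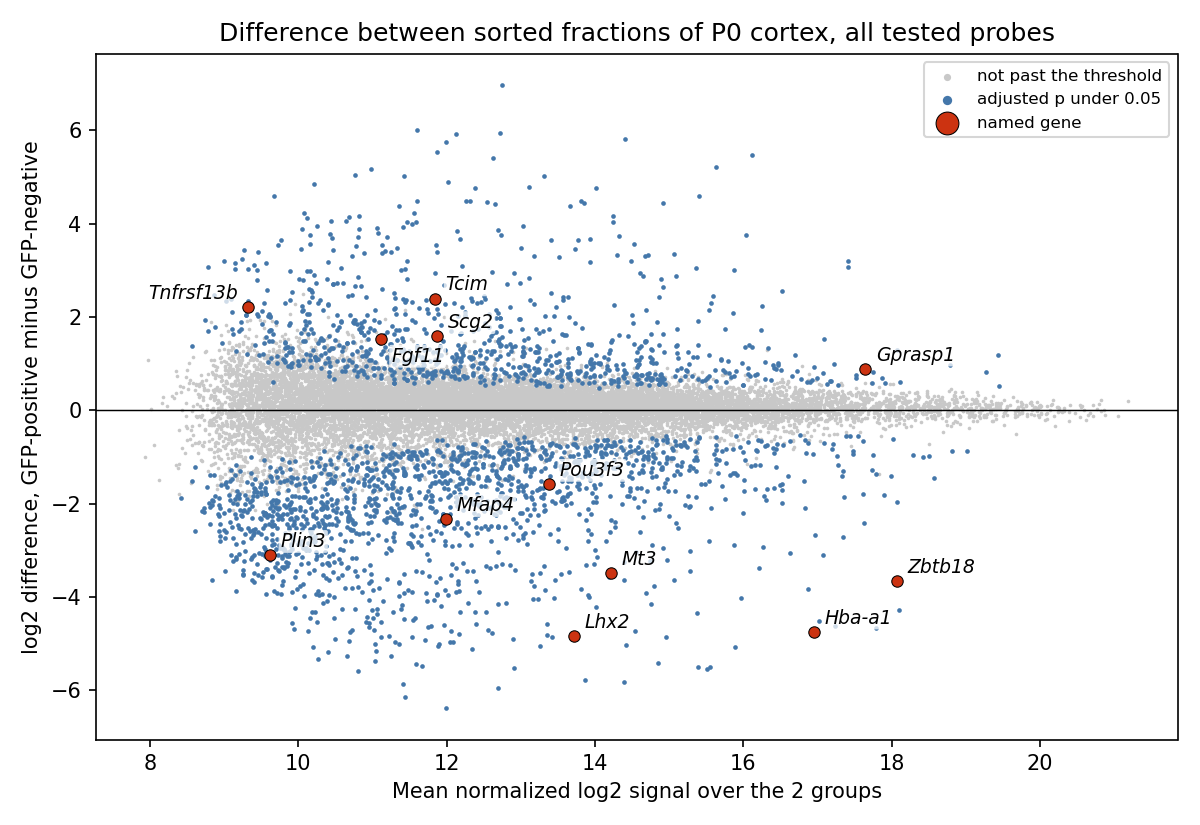
Log2 difference between GFP-positive and GFP-negative cells (y axis) against the mean normalized log2 signal of both groups (x axis) for the 16875 tested probes, with the 2441 probes past the limma threshold in blue and 12 named genes in red. Lhx2, Hba-a1 and Zbtb18 lie at differences of −4.85, −4.75 and −3.67, and Tcim at 2.39.

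Of the fixed list of 21 excitatory neuron transcription factors, 2 were tested, Lhx2 and Pou3f3, and both were lower in GABAergic neurons than in the other cells. Lhx2 (NM_010710.2), a LIM-homeodomain factor of cortical progenitors, was 28.8-fold lower in GFP-positive cells, with a log2 signal of 11.30 ± 0.97 against 16.15 ± 0.16 (SD, n = 4 each; log2 difference −4.85 ± 0.43 SE; limma adjusted p = 0.000116). Pou3f3, a POU factor of upper-layer neurons, was 3.00-fold lower (−1.58 ± 0.29; limma adjusted p = 0.00595). One GFP-positive array, replicate 2, read 13.19 for Pou3f3, against 12.34 to 12.44 on the others. Without replicate pair 1 the Pou3f3 difference was −1.48 (limma adjusted p = 0.0546). It was −1.66 within replicates 1 and 2 alone and −1.51 within replicates 3 and 4 alone (limma adjusted p = 0.0881 and 0.0808). The Lhx2 difference was −4.56 within replicates 3 and 4 alone (limma adjusted p = 0.0542), and Lhx2 passed within replicates 1 and 2 alone. On all arrays both genes passed over all probes and also when adjusted over the list alone. Zbtb18 (NM_013915.1), a zinc-finger repressor expressed in glutamatergic cortical neurons, lay outside the lists and was 12.7-fold lower (log2 16.24 ± 0.14 against 19.91 ± 0.19; difference −3.67 ± 0.16; limma adjusted p = 8e-06).

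The other named genes with lower signal in GABAergic neurons had varied known roles. The alpha-globin gene Hba-a1 (NM_008218.1), the only tested member of the erythrocyte list, was 26.9-fold lower (log2 14.57 ± 0.43 against 19.32 ± 0.19; difference −4.75 ± 0.23; limma adjusted p = 1.06e-05). Its GFP-positive signal was above background on all 4 arrays and was 3.72% of the GFP-negative signal, and the array of GFP-negative replicate 2 read lowest of its group. A probe for Hba-a1 may also bind the near-identical Hba-a2. Mt3, a metallothionein of the brain, was 11.2-fold lower (−3.49 ± 0.36; limma adjusted p = 0.000261). Mfap4, a protein of extracellular microfibrils, was 5.06-fold lower (−2.34 ± 0.18; limma adjusted p = 5.67e-05). Cebpb, a bZIP transcription factor of myeloid cells and other tissues, was 5.82-fold lower (−2.54 ± 0.53; limma adjusted p = 0.0114), and −2.23 with an adjusted p of 0.0934 without replicate pair 3. The Cebpb difference was −1.62 within replicates 1 and 2 alone (adjusted p = 0.103) and −3.46 within replicates 3 and 4 alone.

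A further 4 lower genes were not above background on any GFP-positive array, so their folds are given as bounds. The lipid-droplet coat protein gene Plin3 was at least 8.63-fold lower. Bcl2a1b, an anti-apoptotic BCL2 relative of blood cells with near-identical copies, was at least 6.63-fold lower. The bounds were 5.85-fold for Lgals1, which encodes galectin-1, and 5.73-fold for the CDC42 effector gene Cdc42ep1. Their limma adjusted p values were 0.00131, 4.6e-05, 0.00152 and 0.000773 in that order. Within replicates 1 and 2 alone the measured Plin3 difference was −2.34 (limma adjusted p = 0.0667), against −3.11 over all arrays. That of Lgals1 was −2.19 within replicates 3 and 4 alone (adjusted p = 0.137), against −2.55.

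Named genes higher in GABAergic neurons showed smaller differences. Tcim (NM_026931.1) had the largest, 5.24-fold (log2 13.04 ± 0.34 against 10.65 ± 0.38; difference 2.39 ± 0.25; limma adjusted p = 0.000264). Scg2, which encodes the dense-core vesicle protein secretogranin II, was 2.99-fold higher (1.58 ± 0.31; limma adjusted p = 0.00844), and was above background on 2 of 4 GFP-negative arrays. Fgf11, an intracellular fibroblast growth factor homologue, was 2.89-fold higher (1.53 ± 0.34; limma adjusted p = 0.0152). Tnfrsf13b, known as a receptor of B lymphocytes, was also higher, with a log2 difference of 2.21 ± 0.45 (limma adjusted p = 0.0103), but only 1 of 4 GFP-negative arrays was above background. GFP-positive replicate 4 read 10.05 for Tnfrsf13b, against 10.51 to 10.61 on the other GFP-positive arrays. Without replicate pair 2 and without pair 3 the Tnfrsf13b differences were 1.85 and 1.95 (limma adjusted p = 0.0545 and 0.0813). Without pair 3 the Fgf11 difference was 1.60 (limma adjusted p = 0.0816), and without pair 4 that of Scg2 was 1.42 (adjusted p = 0.0617). The Scg2 difference was 0.99 within replicates 1 and 2 alone (adjusted p = 0.136) and 2.17 within replicates 3 and 4 alone.

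The other 6 of the 10 highest genes differed by 0.81 to 1.13 on the log2 scale. Ntn1, the gene of the axon guidance cue netrin-1, was 2.19-fold higher (1.13 ± 0.30; limma adjusted p = 0.0377). Ramp3, a receptor activity-modifying protein gene, was 1.86-fold higher (0.89 ± 0.20; limma adjusted p = 0.0154). Gprasp1, a sorting protein of G protein-coupled receptors, was 1.85-fold higher (0.89 ± 0.16; limma adjusted p = 0.00533). The olfactory receptor gene Olfr982, the retrotransposon-derived Rtl8c and the TSPY-like gene Tspyl2 were 1.88-, 1.76- and 1.75-fold higher (limma adjusted p = 0.0255, 0.0236 and 0.0246). With the pairs as a block all 6 passed limma's threshold, with adjusted p from 0.00447 for Ntn1 to 0.0194 for Olfr982. The losses that follow come from fits without the pairs. All 6 lost the limma call when arrays were scaled to the kit control spots, with differences of 0.69 to 1.01 and adjusted p from 0.0927 to 0.233. The call of Ntn1 was also lost without any 1 of the arrays GFP-negative 1, 2 and 4 and GFP-positive 1, 3 and 4 (adjusted p 0.0663 to 0.0996). That of Tspyl2 was lost without GFP-negative 2, 3 or 4 or GFP-positive 1, 2 or 3 (0.0508 to 0.0724). Ramp3 lost it without replicate pair 1 or 3 (0.0606 and 0.123). Olfr982 lost it without GFP-negative 2 or 4 or GFP-positive 1, 3 or 4 (0.0569 to 0.0695), and Rtl8c without GFP-negative 1 or GFP-positive 1, 3 or 4 (0.0537 to 0.0702).

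**Figure D2:**
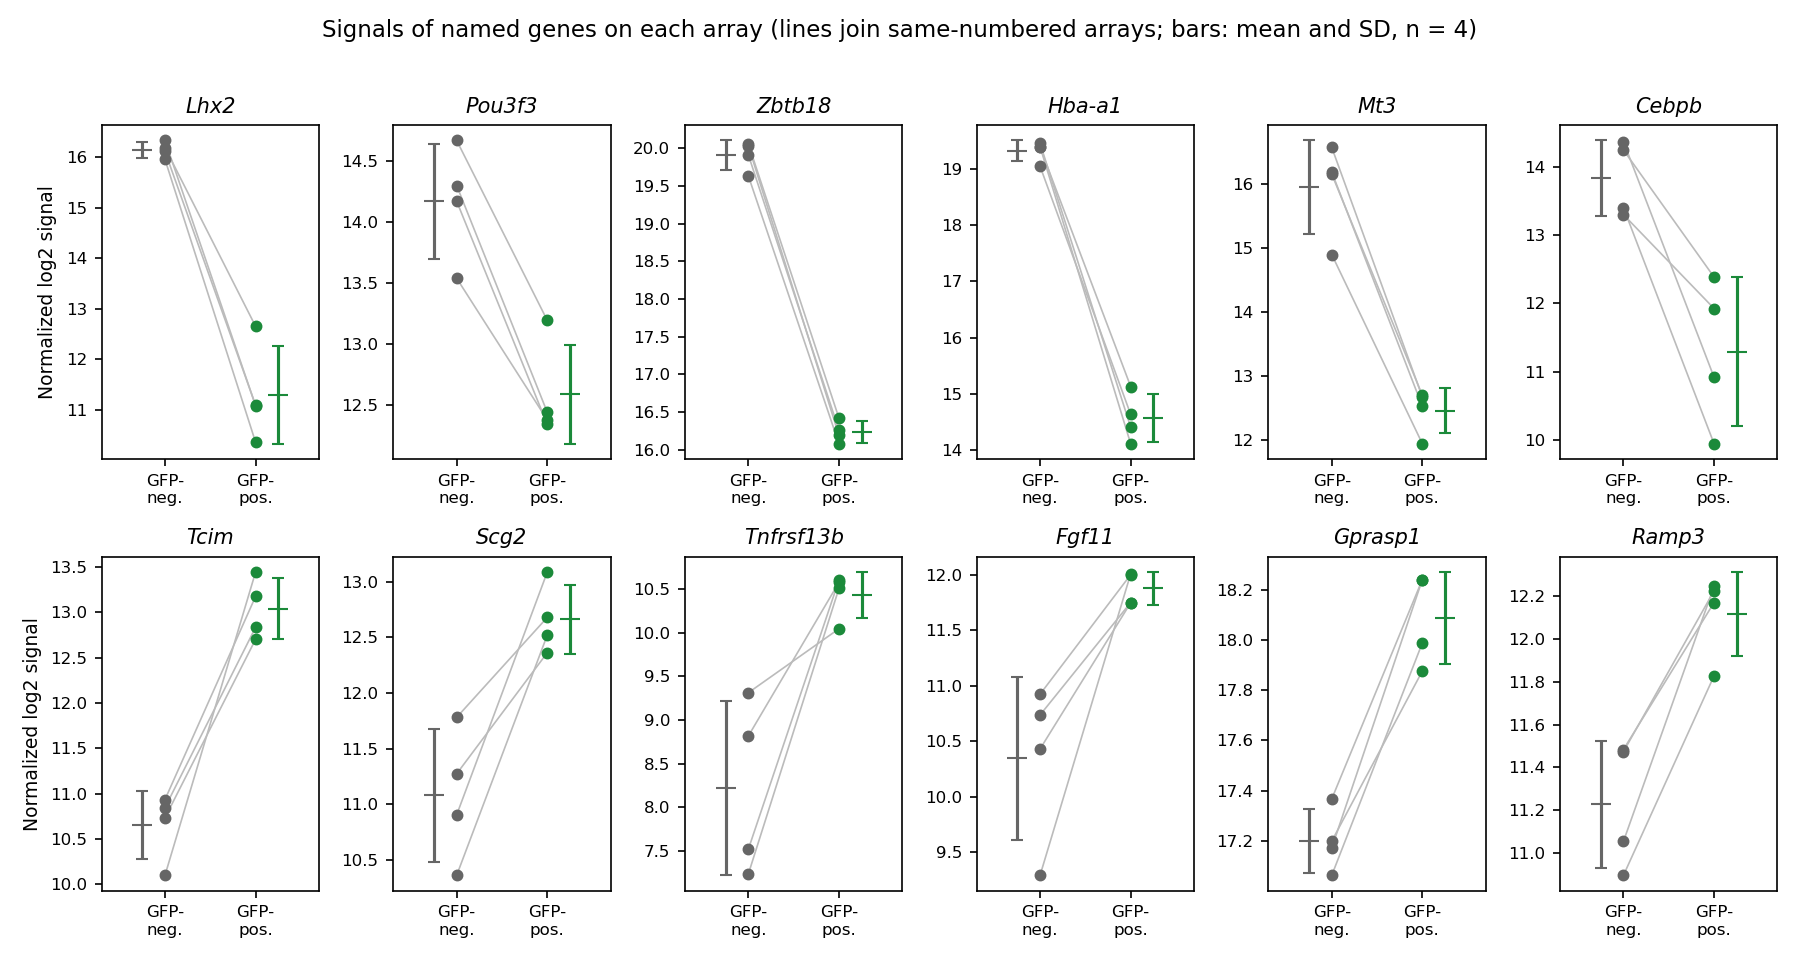
Normalized log2 signal (y axis, a separate range for each gene) of 12 named genes on the 4 GFP-negative (grey) and 4 GFP-positive (green) arrays, with lines joining arrays of the same replicate number and bars giving the mean and SD. The GFP-negative arrays lie above the GFP-positive ones for Lhx2 through Cebpb and below them for Tcim through Ramp3, with mean differences from −4.85 to 2.39.

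Few members of the other fixed lists were measured under a usable name. Of the 29 lists, 23 had no member among the named probes, and no list had the 3 tested members needed for a test of the list. The lists of GABA synthesis and transport, of interneuron transcription factors and of interneuron subtype markers had no such member. In the list of dissociation and immediate early genes, Jun had a log2 difference of −0.34 ± 0.26 (limma adjusted p = 0.470). Among histone genes, H2bc18 was 2.64-fold lower (−1.40 ± 0.25; limma adjusted p = 0.00528), while H2bc13 had a difference of 0.10 ± 0.19 (adjusted p = 0.795). H2B genes are near-identical copies, so the gene behind each probe is uncertain. Without replicate pair 1 the H2bc18 difference was −1.27 (adjusted p = 0.0539). The clustered protocadherin gene Pcdha3 had a difference of 0.42 ± 0.14 (limma adjusted p = 0.0934, and 0.0333 with the pairs as a block), and was higher in 4 of 4 pairs. Its GFP-negative signals were 16.51 to 16.53 on 3 arrays and 16.70 on that of replicate 4. When adjusted over the list alone, 1 of the 2 tested histone genes passed, H2bc18. The erythrocyte, immediate early and protocadherin lists had 1 tested member each, so such an adjustment leaves the unadjusted p. Snap25, the only matched pan-neuronal gene, was not well above background and was not tested.

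Of the 22 named genes past the limma threshold, 9 passed within replicates 1 and 2 alone and 10 within replicates 3 and 4 alone. In both batches 7 passed, and all 22 kept their direction. Of all 2441 called probes, 999 and 1076 passed within the batches, in fits of 4 arrays without the pairs. The calls were made on these same arrays, so the agreement in direction is partly built in. Over all probes with a gene symbol, 32 of 160 genes passed, 12 higher and 20 lower in GFP-positive cells. With the pairs as a block 50 passed, 19 higher and 31 lower.

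Probes without a gene symbol showed larger differences than any named gene. The Celera gene model mCG22275.2 was not above background on any GFP-negative array and was at least 125-fold higher in GFP-positive cells (log2 16.23 ± 0.33; limma adjusted p = 6.54e-06). The model mCG3840.2 had a log2 difference of 6.01 ± 0.26 (limma adjusted p = 7.7e-06), with 1 of 4 GFP-negative arrays above background. On the other side, mCG53790.2 had a log2 difference of −6.39 ± 0.81 (limma adjusted p = 0.000773), with 2 of 4 GFP-positive arrays above background and a GFP-positive SD of 1.91, and mCG6271.2 was at least 70.6-fold lower and not above background on any GFP-positive array (adjusted p = 2.37e-05). The bounds of mCG22275.2 and mCG6271.2 equal their measured folds. Over all 33012 gene probes, 265 were above background on all 4 GFP-negative and 0 of 4 GFP-positive arrays, and 52 showed the opposite. Among the other splits of the 8 arrays into 4 and 4, the highest count on any one side was 65, under the 265 but over the 52. The count of 52 is therefore not shown to stand out, and how many other splits reach it is not given here. With the minimum raised to 5 times the noise the counts were 262 and 80, with no other splits given for comparison.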

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

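The tests of the calls of at least 2-fold under other scalings, the kit control scaling, the paired shares and the ratios of probes above background on all 8 arrays were chosen after results were seen; the other tests in this part were set down before.

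In 56 sets of 4 arrays, 4 values lay far from the other 3 of their group, and chance gives about 1 in 20. Hba-a1 in GFP-negative replicate 2 read 19.05 against 19.39 to 19.46 on the other arrays of the group, a gap of 0.833 of the range. Pcdha3 in GFP-negative replicate 4 read 16.70 against 16.51 to 16.53, a gap of 0.884. Pou3f3 in GFP-positive replicate 2 read 13.19 against 12.34 to 12.44, a gap of 0.883. Tnfrsf13b in GFP-positive replicate 4 read 10.05 against 10.51 to 10.61, a gap of 0.830.

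More probes were lower than higher in GABAergic neurons, with 31.8% of the calls of at least 2-fold higher against 56.1% of the 531 smaller ones (34.0% of 50 with kit control scaling, 48.0% of 98 with no filter, 44.6% of 74 without replicate pair 3). For calls of at least 2-fold, the highest share that were higher was 37.2% over 3 other scalings and 35.7% with probes above background on all 8 arrays, unpaired or paired. This argues against these scalings and this filter on dim probes as the whole cause of that part. The median log2 difference of the tested probes was −0.006 with kit control scaling and 0.181 with median scaling, against 0.088 after quantile normalization. The scalings thus differed little, and a larger shift between the fractions was not tested. For all calls, the unpaired shares stayed at 37.0% or less over the scalings and 43.8% under the strict filter, but the paired fits gave 53.0% and 54.1%, so the bound set for the unpaired fits was too narrow a test and neither explanation is excluded there; the strict filter also removes probes that fell to background. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many calls, the real one with 2441, and the highest other, replicates 1 and 2 against 3 and 4, gave 522; this counts calls, not their direction, and leaves out the pairing, and the 8 splits that part all 4 pairs, where the highest other gave 0, are too few for a share under 0.05. A wider mix of cell types in the GFP-negative fraction is a biological explanation that stays open and was not tested.

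The alpha-globin signal left in GFP-positive cells may come from GFP-negative cells carried over in their own proportions or from erythrocyte RNA carried over by itself. Whole-cell carry-over would leave no probe with a ratio clearly below that of Hba-a1, 3.72% (95% interval 2.57 to 5.37). The number of probes whose interval lay wholly below that of Hba-a1 was 0, but 46 probes had a lower ratio. Of these, 12 were above background on all 8 arrays, with ratios down to 1.75% (1.12 to 2.75). Whole-cell carry-over is therefore neither shown nor excluded. Over the 4 pairs, Hba-a1 in GFP-positive cells correlated at r = −0.157 with that in GFP-negative cells (one-sided exact permutation p = 0.667; the smallest possible is 0.042), which decides nothing about erythrocyte RNA either. Transcription of Hba-a1 in GABAergic neurons was not tested.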

How the results depend on the processing

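The kit control scaling, the batch block, the fits within batches and detection at 5 times the noise were chosen after seeing the data. No probe called both in the unblocked fit to all 8 arrays and under another setting had opposite signs. The count of 2441 moved by over 1.5 times with the replicate block (4043, of which 1830 higher), with that block and median scaling (4156, 2202 higher), at an adjusted p of 0.01 (1481, with 463 higher and 1018 lower), and within pairs 1 and 2 alone (1088, with 339 higher and 749 lower) or 3 and 4 alone (1173, with 354 and 819), where all calls were at least 2-fold and only 4 arrays entered. The count also moved this far without pair 3 (1529, with 462 higher and 1067 lower). It was 2426 with 75th percentile scaling, 2438 with flagged spots missing, 2468 with the offset, 2444 with the floor, 2655 with the intensity trend, 2055 with median scaling, 2039 with the matrix ratios and 1887 with no filter. Kit control scaling gave 1863, with 439 higher, and the batch block 1434 higher. With signal to noise of 3 on all 8 arrays, 12509 probes were tested, and 950 were lower, 362 at least 2-fold higher and 654 at least 2-fold lower. Leaving out 1 array or 1 pair gave counts of 1529, without pair 3, to 2416, with 462 to 921 higher; the smaller counts come with fewer samples. Detection at 5 times the noise gave 80 probes above background on GFP-positive arrays alone in place of 52. Apart from these constructions the cause was not tested.

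Of 22 named genes past the limma threshold, the pairing as a block ended no call and it added that of Pcdha3 (0.0333), as did that block with median scaling (0.0336), the intensity trend (0.0248) and the batch block (0.0461). None changed sign under any alternative. Calls ended for Olfr982 and Tspyl2 with median scaling and the matrix ratios, for Olfr982 with the intensity trend, for 5 genes with no filter, for 6 with kit control scaling, for 4 without some single array and for 11 without some pair. All of these losses come from fits without the pairs, which leave differences between replicates in the error, and the leave-out fits also hold fewer arrays. The difference of H2bc13, never past the threshold, was −0.038 within pairs 1 and 2 alone, and −0.026 to 0.20 when arrays or pairs were left out. The array tables hold no second, normalized signal and no list had 3 tested members, so the settings that needed them were not run. Signal over background limited the test to 16875 of 33012 probes.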

Other observations

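The test of the Prader-Willi genes was chosen after the results were seen, and so were Ramp1, Heg1, B9d1 and the other genes outside the naming rule.

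A further 10 genes with a symbol passed the limma threshold outside the rule for named genes. The receptor activity-modifying proteins went opposite ways: Ramp1 was at least 2.79-fold lower in GFP-positive cells and not above background there (limma adjusted p = 0.0193), while Ramp3 was 1.86-fold higher. Both proteins are partners of the calcitonin receptor-like receptor. Heg1, a membrane protein gene of endothelial cells, was 3.85-fold lower (log2 difference −1.94 ± 0.21; limma adjusted p = 0.000369), and B9d1, a gene of the ciliary transition zone, was 4.50-fold lower (−2.17 ± 0.55; limma adjusted p = 0.0295), with 2 of 4 GFP-positive arrays above background. Nt5dc3, Crip1, Tmem254a, Rap2b and Llgl1 were also lower, by −1.75, −1.43, −1.04, −0.99 and −0.75, and Akap7 and Nanos1 were higher, by 0.81 and 0.71. Each had the same sign in 4 of 4 pairs, which was no condition for naming them here.

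Olfactory receptor genes were rarely measured above background in either fraction. Of 39 named olfactory receptor probes 3 were tested (7.69%), against 51.4% of all 317 named probes, and 1 of these, Olfr982, was higher in GFP-positive cells. Of 12 vomeronasal receptor probes 1 was tested, and of 10 probes for keratins and keratin-associated proteins 2 were, both for keratin-associated proteins, with 0 calls.

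The paternally expressed genes of the Prader-Willi domain may be higher in GABAergic neurons as a set. The log2 differences were 0.57 ± 0.17 for Ndn (limma adjusted p = 0.0592, and 0.0295 with the pairs as a block), 1.94 ± 0.60 for Magel2 (0.0648 and 0.0740), 0.27 ± 0.15 for Mkrn3 and 0.33 ± 0.26 for Peg12, against 0.05 ± 0.17 for the neighbouring Ube3a. Magel2 was above background on 1 GFP-negative and 3 GFP-positive arrays. The median of the 4 was 0.45, which 4.62% of 10000 random lists matched on mean signal reached. The camera test with the preset correlation gave p = 0.0615 in the paired and 0.0445 in the unpaired fit, and with an estimated correlation p = 0.334 and p = 0.247. With 4 members the shift of the set is not settled.

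The in vitro transcription control spots read a mean log2 signal of 17.11 on GFP-negative replicate 2, against 13.87 to 15.44 on the other 7 arrays.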
